A study of Mus musculus with 6 samples.

How the data were processed

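RNA from 6 cultured lines of mouse spermatogonial stem cells was analysed, 3 wild-type and 3 labelled Ephb2-KO. Per the labels' protocols, total RNA was isolated with a column kit and polyadenylated RNA was made into libraries with a directional (strand-keeping) kit. Lines were made by electroporating a fluorescent reporter plasmid with or without a guide RNA against Ephb2, sorting and subcloning. The labels describe the lines as separate subclones of sorted cells; they do not say whether lines with the same number share a parent culture, nor on which days libraries were made.

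The deposited values are raw read counts per gene, with the summed exon length of each gene beside them. Per the file headers, the authors counted reads from 1 merged alignment per library with featureCounts 1.4.6-p4 over exons grouped by gene name, using the GENCODE vM3 annotation with strand setting 2 (reversely stranded). They ran it without the options for read pairs, multi-mapping reads or overlapping features. A count is therefore of reads rather than fragments. Reads that map to several places or to overlapping genes of the same strand were left out, and genes with near-identical copies are undercounted; antisense genes are kept apart by strand. Per the submitters' processing notes, STAR and FastQC were used and the build was GRCm38.p3; their versions and the alignment settings are not given in the sources used here. Coordinates are those of the deposited files (GRCm38, 1-based). The files held 41053 gene names and no summary lines, so every count belonged to a named gene, and 0 columns held samples of another series.

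Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (15263 tested), libraries were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest compared the groups with no covariate; Benjamini-Hochberg adjustment ran over all tested genes and the threshold was 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes and log2 CPM a prior count of 2. Gene lists (30, of which 28 had at least 5 tested members) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With the estimated correlation 0 lists passed, and 0 with fry, with or without the block. That setting also missed a simulated shift, as given below. Its adjusted p therefore shows neither correlation between genes nor an absence of change. DESeq2 1.42.0 was an alternative. Figures were drawn with matplotlib 3.10.9.

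The groups, lists, tests, alternatives and rule for named genes were set before the data were examined. The rule named Ephb2, up to 12 higher and 12 lower genes past the threshold with separate CPM ranges and a mean of at least 5 CPM, or, with fewer than 5 genes past it, the 10 with the smallest p as values. It named from each list up to 4 passing members or otherwise up to 2 with the smallest p, and a fixed set of stem cell, cell cycle and Eph genes. Fewer than 5 genes passed, so values are given for the 10. Members of lists named beyond these (Fn1, Loxl1, Col3a1, Col1a2, Pdgfra, Postn, Vim, Cyp26a1, Itga5, Rarg and Nanos3 in the report) were chosen after their values were seen.

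Whether replicate numbers pair the libraries was checked by correlating deviations from the group means over genes. Same-numbered libraries correlated at 0.596, 0.736 and 0.850 for numbers 1, 2 and 3, against at most 0.0790, 0.0790 and -0.460 with another number, so by the set bound of 0.1 the numbers pair the libraries, and the fit with the number as a block is given where it changes a call. The pairing comes from the shared numbers in the sample titles and from this check. The biological coefficient of variation was 0.440 without the block and 0.166 with it. GC content and gene length were checked by spline regression of log2 differences on the GC content of the longest reference transcript of each gene and on log2 exon length. No libraries were duplicates: chi-square per degree of freedom between libraries ranged from 22.1 to 307.

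The scripts were tested on simulated counts for the real genes, drawn from the real pair means and library sizes with the blocked dispersion, with 200 genes changed, 100 by 2-fold and 100 by 4-fold. The changed genes were picked above a floor of mean CPM and with counts in every pair. Recovery therefore does not speak for the genes lowest in counts. For the comparison of the groups over 15263 genes, the blocked fit recovered 85% of the 2-fold and 95% of the 4-fold genes with 14 false calls among 194, and the fit without the block recovered 0% of either, since differences between pairs entered its spread. With pair means set equal, the fit without the block recovered 84% and 98%, with 20 false calls among 202, and the blocked fit gave 19 among 198. False calls made up 7.22% of blocked calls with the real pair means and 9.60% with equal means. Each lay above the share of 0.05 that the threshold aims at. A list shifted by 0.5 in log2 was called by camera with the preset correlation and not with the estimated one (adjusted p = 0.189 without the block and 0.148 with it). Genes were drawn independently within a pair, so this does not show how often the preset 0.01 gives false list calls in correlated lists. The estimated correlation of the real matrix list was 0.46 (0.33 with the block), and that of the Y-linked list 0.66 (0.0030 with the block). The blocked Y-linked value lay below the preset 0.01, yet the unadjusted camera p went from 5.15e-05 to 0.0536 with it. A lost call under that setting therefore need not come from correlation.

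Depth ranged from 21772404 to 34047758 counts per library, and a floor of 3 counts marks what a count of 0 allows. A fold against a group at 0 in all libraries was computed against 3 counts over the group. Alternatives covered the test, scaling, filters, the block, passage as a covariate, each library left out, shifted chromosomes left out, the list test and its correlation. Alternatives chosen after seeing the data were leaving out both replicate 3 libraries, leaving out 1 pair at a time in the blocked fit, the block joined with other tests, scalings and filters, the block without genes high in the replicate 3 libraries, and limma voom with the number as a random effect. Groups of 3 are too small for a test of single outlying libraries, and none was made.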

Results

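Gene expression was measured by strand-specific sequencing of polyadenylated RNA from cultured mouse spermatogonial stem cells, the germline stem cells of the adult testis, grown outside the body. Cells had received a plasmid encoding green fluorescent protein, either alone or with a guide RNA against Ephb2, and fluorescent cells were sorted and subcloned. The series held 3 wild-type lines and 3 lines labelled Ephb2-KO, each sequenced as 1 library, with replicates numbered 1 to 3 in each group. Replicates 1 and 2 of both groups were at passage 20 and replicate 3 of both groups was at passage 18. Total counts were 34047758, 26218662 and 24928648 in wild-type replicates 1, 2 and 3, and 33140336, 23199572 and 21772404 in Ephb2-KO replicates 1, 2 and 3. Expression is given as CPM, the count scaled to library size. A count of 3 corresponded to between 0.0803 and 0.147 CPM in a single library, and floors below cover counting error only. The comparison addressed how the transcriptome of these cells differs when the guide against Ephb2, a receptor tied by the study's title to proliferation and stem cell activity, has been used.

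Ephb2 encodes an Eph family receptor tyrosine kinase that binds ephrin ligands on neighbouring cells, and it lies on the minus strand of chromosome 4 from 136647539 to 136835988 in GRCm38. Its transcript was not lower in the libraries labelled Ephb2-KO. Ephb2 stood at 21.3, 27.1 and 10.8 CPM in wild-type replicates 1, 2 and 3 (19.7 ± 8.27, SD, n = 3) and at 37.1, 16.5 and 13.4 CPM in the libraries labelled Ephb2-KO (22.3 ± 12.9, SD, n = 3). Between libraries with the same replicate number, Ephb2 differed by a log2 value of 0.80 in pair 1, -0.71 in pair 2 and 0.31 in pair 3. The log2 fold change was 0.18 with an SE of 0.50 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.0). An exact two-sided permutation test gave p = 0.9, where 3 libraries against 3 cannot go below 0.1. The 95% interval of the fold ran from 0.499 to 2.57, and from 0.723 to 1.68 in the fit with the replicate number as a block, where the log2 fold change was 0.14 (SE 0.27). A 2-fold change in either direction lay outside the blocked interval, which borrows its spread from other genes. The direction rested on single libraries: it was -0.11 without wild-type replicate 3 and -0.40 without Ephb2-KO replicate 1. Counts summed over all annotated exons do not show a small insertion or deletion at a guide's target, so the mRNA level neither bore out nor excluded the genotype. The words "labelled Ephb2-KO" name the lines by their labels in every direction given below.

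**Figure D1:**
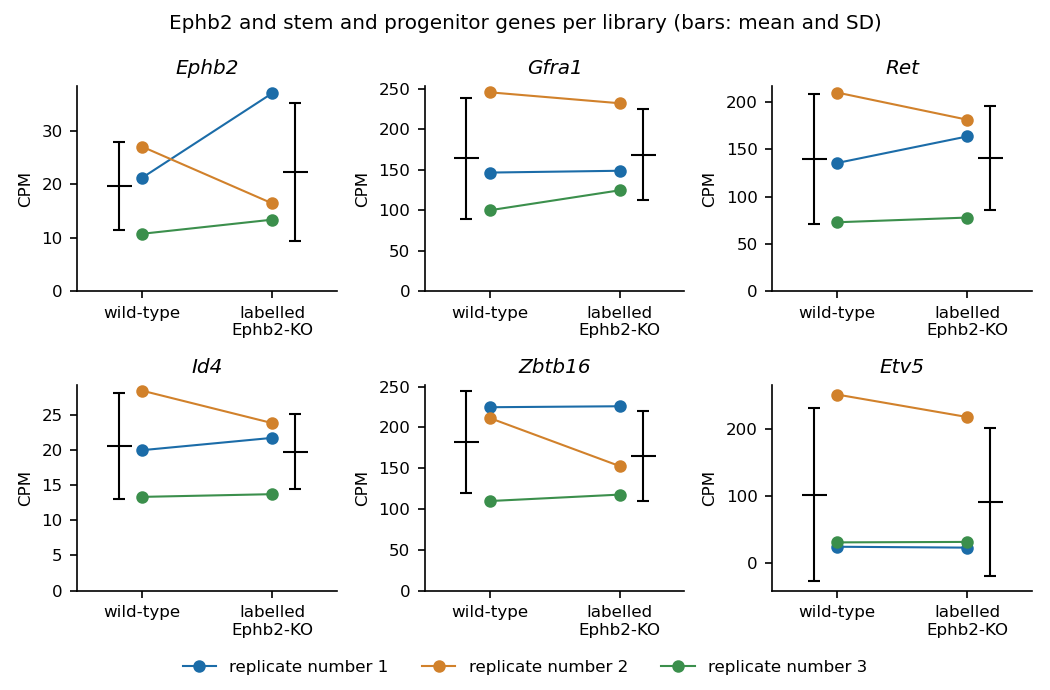
CPM of Ephb2 and of 5 stem and progenitor genes in each library; points joined by a line carry the same replicate number, and bars beside them give the group mean and SD (n = 3). Ephb2 spans 10.8 to 27.1 CPM in wild-type libraries and 13.4 to 37.1 CPM in libraries labelled Ephb2-KO, and Etv5 is far above its other values in both replicate 2 libraries.

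A small number of genes were near silent in the 3 libraries labelled Ephb2-KO and present in all 3 wild-type libraries. Ccdc172, which encodes a coiled-coil protein (chromosome 19, 58512002 to 58553085), had 140, 74 and 125 counts in wild-type replicates 1, 2 and 3 and 0 counts in each of the 3 others, which was at least 101-fold lower against a floor of 3 counts over the group. Zfp42, also called Rex1 and used as a marker of pluripotent cells (chromosome 8, 43295068 to 43307009), had 107, 19 and 13 counts against 0 in each, at least 41.5-fold lower by the same floor. That bound holds for the pooled groups and rests largely on wild-type replicate 1. Zfp42 stood at 2.87, 0.745 and 0.536 CPM in wild-type replicates 1, 2 and 3. Krt18, a keratin of simple epithelia (chromosome 15, 102028216 to 102032026), had 125, 60 and 70 counts against 2, 6 and 2, and A230065H16Rik (chromosome 12, 111406809 to 111412077) had 69, 215 and 238 counts against 0, 0 and 6. In the opposite direction Ush1c, which encodes the scaffold protein harmonin (chromosome 7, 46195350 to 46238503), stood at 2.71, 0.588 and 0.413 CPM in wild-type libraries and at 11.2, 3.51 and 2.50 CPM in those labelled Ephb2-KO. It lay outside the rule for named genes and was chosen after its values were seen.

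Across 15263 tested genes the edgeR quasi-likelihood test without a block called 0 genes at a Benjamini-Hochberg adjusted p under 0.05. In counts simulated with the real pair means, that fit recovered 0% of 2-fold and 0% of 4-fold genes. Its count of 0 therefore does not show an absence of change. At an unadjusted p under 0.05 there were 32 genes (7 higher, 25 lower), where independent libraries with no difference would give 763 and the other splits that part every pair gave 11, 26 and 34. DESeq2 called 4 genes, all lower: Ccdc172, A230065H16Rik, Krt18 and Zfp42. Because same-numbered libraries deviated together, the fit with the replicate number as a block is given beside it. It called 4 genes, each past a log2 fold change of 1 in size, with 987 at an unadjusted p under 0.05 (668 higher, 319 lower). The other splits that part every pair gave 143, 382 and 1588 genes at that unadjusted p. Of the 4 called, Ush1c rose (log2 fold change 2.35, SE 0.29, adjusted p = 0.0270, higher in 3 of 3 pairs). The other 3 fell, each in 3 of 3 pairs: Ccdc172 (adjusted p = 0.00736), A230065H16Rik (adjusted p = 0.00912) and Krt18 (log2 fold change -4.41, SE 0.55, adjusted p = 0.0270). Zfp42 did not pass in the blocked quasi-likelihood test (adjusted p = 0.0555). Over the alternatives run, adjusted p ranged from 7.81e-22 to 1.0 for Ccdc172 and from 9.38e-41 to 1.0 for A230065H16Rik. It ranged from 1.49e-08 to 1.0 for Krt18, from 2.25e-06 to 1.0 for Ush1c and from 4.13e-07 to 1.0 for Zfp42. The blocked count was 56 without the replicate 1 libraries, 3 without the replicate 2 libraries and 4 without the replicate 3 libraries. It was 0 with a filter of 5 CPM in at least 3 libraries, which leaves these 4 genes untested.

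**Figure D2:**
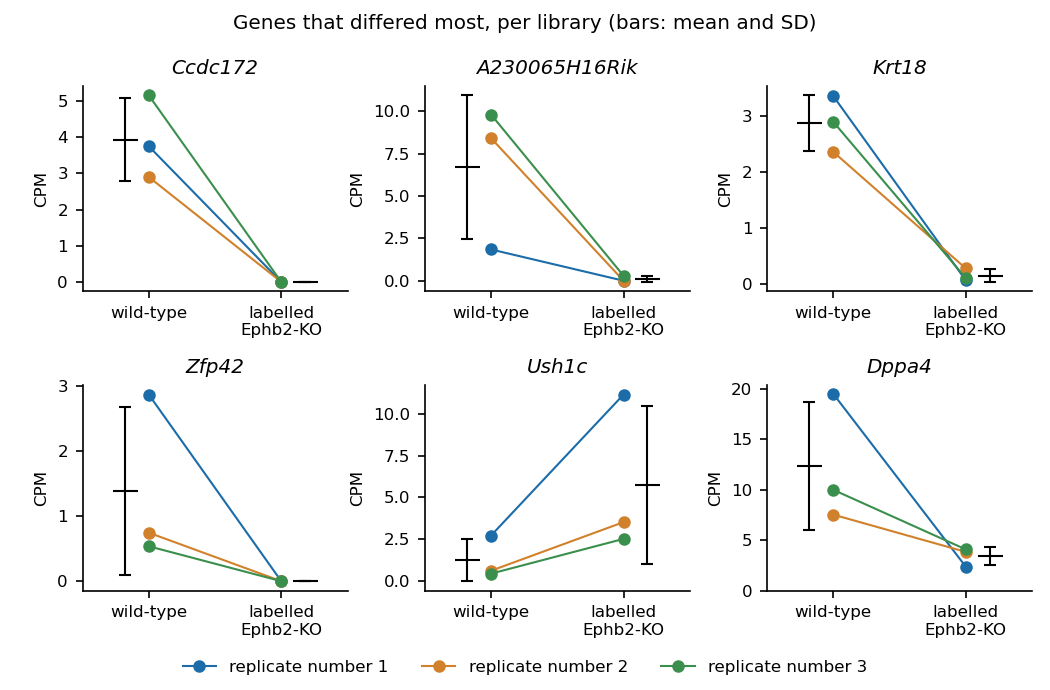
CPM of 6 genes in each library; points joined by a line carry the same replicate number, and bars give the group mean and SD (n = 3). Ccdc172 and Zfp42 are at 0 in the 3 libraries labelled Ephb2-KO, A230065H16Rik and Krt18 are at or below 0.295 CPM there, and Ush1c is higher in 3 of 3 pairs.

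The other genes among the 10 with the smallest p in the unblocked fit were all lower in the libraries labelled Ephb2-KO. Their CPM ranges did not overlap, which a choice by smallest p favours, so it is no separate support. For genes not picked by p, chance gives that arrangement in 10% with 3 exchangeable libraries against 3, which paired libraries are not. Dppa4, a nuclear protein expressed in pluripotent cells, stood at 12.3 ± 6.32 CPM (SD, n = 3) in wild-type libraries and at 3.42 ± 0.923 CPM (SD, n = 3) in those labelled Ephb2-KO (log2 fold change -1.85, SE 0.48). The zinc finger gene Bnc1 stood at 32.7 ± 7.11 against 17.5 ± 2.21 CPM (SD, n = 3), a log2 fold change of -0.90 (SE 0.26). Fxyd2, a regulatory subunit of the sodium pump, had 42, 14 and 20 counts against 3, 0 and 0. Log2 fold changes of 1700034O15Rik, the transcription factor gene Onecut2 and Cdc20b were -2.41 (SE 0.59), -1.56 (SE 0.43) and -2.66 (SE 0.80). None of these 6 genes passed (edgeR adjusted p = 1.0 for each), and in the blocked fit their adjusted p was 0.316 for Fxyd2 and 0.741 for the other 5.

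No gene of stem or progenitor spermatogonia passed over all genes, and the medians of their lists lay close to 0. Of 18 tested stem spermatogonia genes, 10 lay above a log2 fold change of 0 and 8 below, and 0 passed. The list median was 0.02 (camera adjusted p = 0.837). Gfra1 and Ret, which form the receptor for glial cell line-derived neurotrophic factor, had log2 fold changes of 0.04 (SE 0.38) and 0.01 (SE 0.45), and Id4, a repressor marking stem spermatogonia, had -0.06 (SE 0.37). Values for the transcription factor genes Etv5, Bcl6b and Lhx1 were -0.17 (SE 1.14), 0.15 (SE 0.47) and 0.07 (SE 0.81), for the RNA-binding protein gene Nanos2 -0.33 (SE 0.33) and for Pax7 0.63 (SE 0.60). The blocked fit gave smaller errors, with 0.08 (SE 0.12) for Gfra1, 0.05 (SE 0.13) for Ret, -0.09 (SE 0.12) for Etv5, -0.03 (SE 0.16) for Id4 and -0.14 (SE 0.42) for Lhx1. In that fit Nanos2 had -0.35 (SE 0.14, unadjusted p = 0.0328), lower in 3 of 3 pairs, and Pax7 had 0.50 (SE 0.22, unadjusted p = 0.0442), higher in 3 of 3 pairs. Among 18 progenitor and undifferentiated spermatogonia genes 0 passed (list median -0.05, camera adjusted p = 0.219), with -0.14 (SE 0.35) for Zbtb16, -0.49 (SE 0.28) for Upp1 and -0.59 (SE 0.34) for Pou5f1. With the block Upp1 had -0.48 (SE 0.19, unadjusted p = 0.0247) and Pou5f1 -0.61 (SE 0.22, unadjusted p = 0.0185), each lower in 3 of 3 pairs, and the adjusted p was 0.741 for these 2 genes, Nanos2 and Pax7. Of 14 differentiating spermatogonia genes 0 passed (list median 0.07, camera adjusted p = 0.383). Log2 fold changes were 0.05 (SE 0.62) for the receptor gene Kit and 0.46 (SE 0.23) for Crabp1. Stra8, a retinoic acid target needed for entry into meiosis, had 0.78 (SE 0.69). With the block 9 of the 14 lay above 0 and 5 below (median 0.09), and the list did not pass by camera. Of the 14, 4 were higher in 3 of 3 pairs, Stra8 and Crabp1 among them, and 0 were lower in 3 of 3 pairs. Blocked values were 0.64 (SE 0.23) for Stra8, 0.48 (SE 0.13) for Crabp1 and 0.07 (SE 0.20) for Kit. All genes named here had an adjusted p of 1.0 by edgeR without the block, a fit that recovered 0% of simulated 4-fold genes. Crabp1 was the only gene of these 3 lists past a blocked p adjusted over the list alone (0.0473).

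Proliferation genes showed no shift that passed. Of 38 DNA replication genes 19 lay above 0 and 19 below (list median -0.00, camera adjusted p = 0.809), and of 34 mitosis genes 13 lay above and 21 below (list median -0.03, camera adjusted p = 0.537). With the block 20 replication genes lay above 0 and 18 below (median 0.01, camera adjusted p = 0.594). In that fit 18 mitosis genes lay above and 16 below (median 0.0034, camera adjusted p = 0.472). Of replication genes 2 were higher and 3 lower in 3 of 3 pairs, and of mitosis genes 1 and 3. Mki67, a marker of cycling cells, had a log2 fold change of -0.10 (SE 0.54), E2f1 0.28 (SE 0.20), Orc1 -0.36 (SE 0.27), Hmmr -0.31 (SE 0.19) and Kif20b -0.40 (SE 0.27). The cyclin genes Ccnd1 and Ccnd2 had 0.36 (SE 0.60) and -0.06 (SE 0.44), and the cell cycle inhibitor genes Cdkn1a and Cdkn1b had 0.24 (SE 0.93) and -0.76 (SE 0.38). The 26 tested cell cycle inhibitors and p53 targets had a list median of 0.06 (camera adjusted p = 0.809), with -0.47 (SE 0.38) for Perp. With the block Ccnd1 had 0.40 (SE 0.11, unadjusted p = 0.00491) and Cdkn1a 0.24 (SE 0.11, unadjusted p = 0.0561), each higher in 3 of 3 pairs. Orc1 (-0.38, SE 0.16), Hmmr (-0.31, SE 0.12) and Kif20b (-0.39, SE 0.13) were lower in 3 of 3 pairs in that fit, with unadjusted p of 0.0329, 0.0291 and 0.0127. None of these genes passed over all genes or adjusted over the list alone, with or without the block. The smallest adjusted p by edgeR over all genes was 0.741.

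Eph receptor and ephrin genes lay above 0 more often than below without passing, and Eph downstream effectors went both ways. Of 18 Eph receptors and ephrins other than Ephb2, 14 lay above 0 and 4 below, and the list median was 0.12 (camera adjusted p = 0.219). In the blocked fit 12 lay above and 6 below (median 0.18, camera adjusted p = 0.0746), and 7 of the 18 were higher in 3 of 3 pairs. Ephb4 had the smallest p of the list: 43.0 ± 8.16 CPM in wild-type libraries and 68.9 ± 19.7 CPM in those labelled Ephb2-KO (SD, n = 3), a log2 fold change of 0.68 (SE 0.28). It was higher in 3 of 3 pairs, with an unadjusted edgeR p of 0.0477 and an adjusted p of 1.0. Ephb3 had 0.44 (SE 0.40), and the ligand genes Efna3, Efnb1 and Efnb2 had 0.28 (SE 0.25), 0.28 (SE 0.51) and 0.20 (SE 0.64). The 27 Eph downstream effectors, 14 above 0 and 13 below, had a median of 0.01 (camera adjusted p = 0.770), with 0.39 (SE 0.26) for Git1 and -0.50 (SE 0.36) for Chn2. In the blocked edgeR fit Ephb4 had 0.65 (SE 0.19, unadjusted p = 0.00674) and Ephb3 0.41 (SE 0.17, unadjusted p = 0.0354). Git1 had 0.42 (SE 0.13, unadjusted p = 0.00917), and these genes were higher in 3 of 3 pairs. Chn2 had -0.47 (SE 0.20, unadjusted p = 0.0407), lower in 3 of 3 pairs. Adjusted over all genes, p was 0.741 for each.

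Extracellular matrix genes had a median above 0 in the library labelled Ephb2-KO of each pair, with 30 of 41 higher in 3 of 3 pairs. Of 41 tested members 38 lay above a log2 fold change of 0 and 3 below, the list median was 0.34, and the list rose by camera with a preset correlation of 0.01 (adjusted p = 0.000124). It had adjusted p = 0.918 with an estimated correlation, a setting that also missed a simulated list shift of 0.5 in log2. In the blocked fit 39 members lay above 0 and the list median was 0.36 (camera adjusted p = 2.07e-14; adjusted p = 0.739 with an estimated correlation), with medians of 0.56, 0.24 and 0.39 in pairs 1, 2 and 3. Adjusted over the list alone, 0 members passed without the block and 23 with it, all higher, against 0 over all genes in either fit. The collagen gene Col1a1, at 1112 ± 784 CPM in wild-type libraries and 1616 ± 975 CPM in those labelled Ephb2-KO (SD, n = 3), had a blocked log2 fold change of 0.62 (SE 0.14, edgeR p adjusted over the list alone = 0.0136). Fn1 (fibronectin) had 0.53 (SE 0.14, 0.0136), Loxl1 0.51 (SE 0.12, 0.0136) and Col3a1 0.34 (SE 0.13, 0.0435). Fn1, Loxl1 and Col3a1 were chosen after their values were seen. Agrn and Eln, the matrix genes with the smallest p without the block, had blocked values of 0.30 (SE 0.16) and 0.75 (SE 0.38). Each was higher in 2 of 3 pairs. The fibroblast or stromal marker list, which shares 4 genes with the matrix list, did not pass without the block (20 tested, 16 above 0, list median 0.16, camera adjusted p = 0.219). It rose with the block (list median 0.34, camera adjusted p = 0.000275; adjusted p = 0.739 with an estimated correlation). Adjusted over the list alone, 0 of its members passed without the block and 5 with it, all higher: Col1a1, Col1a2, Pdgfra, Postn and Vim. Thy1, which had the smallest p of that list without the block, went the other way (blocked -0.43, SE 0.34, higher in 1 of 3 pairs). With the block 17 members lay above 0 and 3 below. Reads in the fibroblast list made up 0.360%, 0.442% and 1.80% of counts in wild-type replicates 1, 2 and 3 and 0.544%, 0.550% and 2.02% in the libraries labelled Ephb2-KO, higher in 3 of 3 pairs. Mitochondrially encoded transcripts (12 genes) were also higher in each pair, with medians of 0.71, 0.48 and 0.34 in pairs 1, 2 and 3, and whether RNA or library quality links them to the list calls was not tested. Without wild-type replicate 1 only the pluripotency list passed, and without Ephb2-KO replicate 3 the matrix list did not pass.

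**Figure D3:**
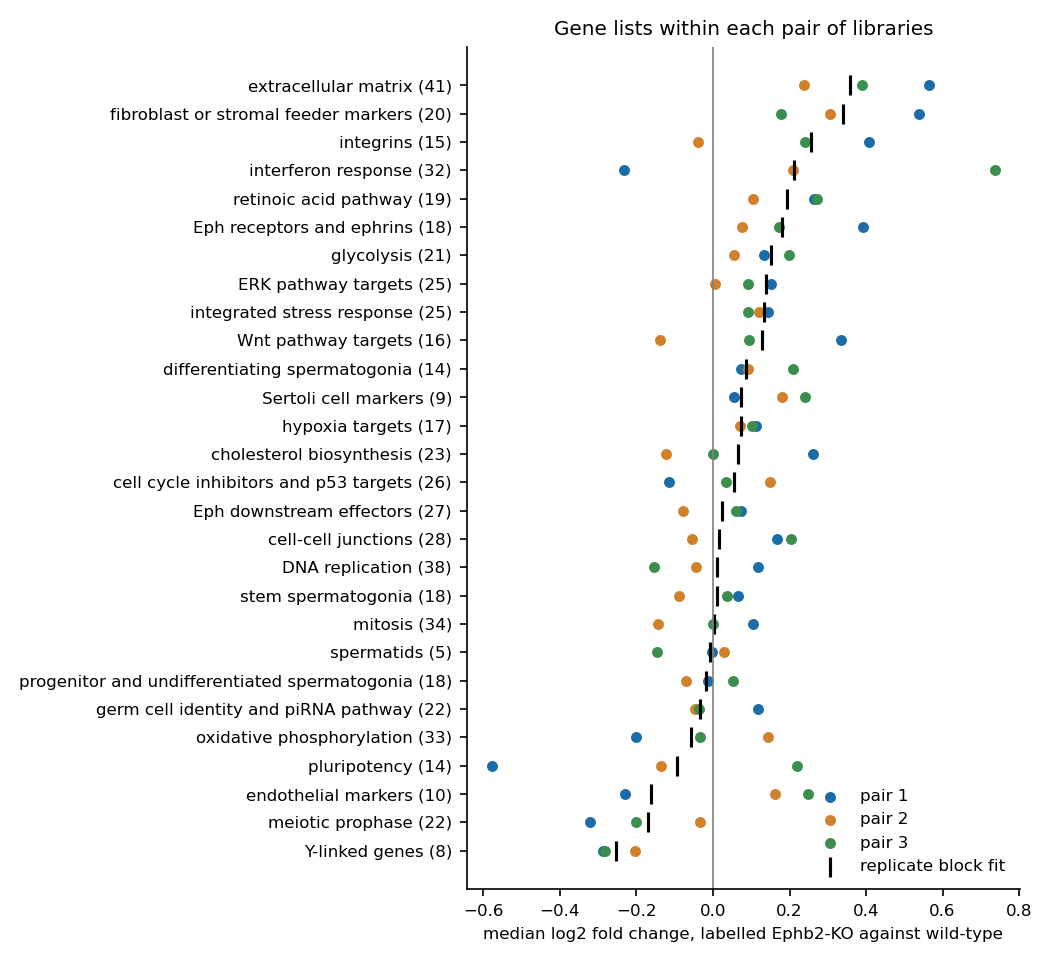
Median log2 fold change over the tested members of each gene list (number in brackets) in the library labelled Ephb2-KO against wild-type, within pairs 1, 2 and 3 (points) and in the fit with the replicate block (black bars). The extracellular matrix list lies at 0.56, 0.24 and 0.39 in pairs 1, 2 and 3, while the interferon response list ranges from -0.23 in pair 1 to 0.74 in pair 3.

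The other lists called higher were interferon response and glycolysis. Of 32 interferon response genes 28 lay above 0 (list median 0.44, camera adjusted p = 0.0424; adjusted p = 0.918 with an estimated correlation). The antiviral genes Oas3 and Oasl2 had log2 fold changes of 0.80 (SE 0.38) and 0.45 (SE 0.29). In the blocked fit the list median was 0.21 (camera adjusted p = 0.0141; adjusted p = 0.822 with an estimated correlation). The list was not higher in every pair, with a median of -0.23 in pair 1, 0.21 in pair 2 and 0.74 in pair 3. Several of its members belong to families of similar sequence whose shared reads were not counted. Of 21 glycolysis genes 17 lay above 0 (list median 0.14, camera adjusted p = 0.0381; adjusted p = 0.918 with an estimated correlation), among them the phosphofructokinase gene Pfkl (0.52, SE 0.33) and the lactate transporter gene Slc16a3 (0.44, SE 0.26). The blocked median was 0.15 (camera adjusted p = 0.0291; adjusted p = 0.739 with an estimated correlation). The integrated stress response list rose only with the block (25 tested, list median 0.13, camera adjusted p = 0.0444; adjusted p = 0.739 with an estimated correlation; 0.219 without the block), with blocked log2 fold changes of 0.52 (SE 0.13) for Cebpb and -0.38 (SE 0.17) for Atf3. The 3 lists had 0 members past an adjusted p over all genes or adjusted over the list alone in either fit, and without the chromosomes listed below as shifted neither interferon response nor glycolysis passed.

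The lists called lower were meiotic prophase, pluripotency and Y-linked genes. Of 22 meiotic prophase genes 19 lay below 0 (list median -0.14, camera adjusted p = 0.00101; adjusted p = 0.918 with an estimated correlation). They included Sycp2, a synaptonemal complex protein gene (-0.73, SE 0.48), and the mismatch repair gene Mlh3 (-0.43, SE 0.27). The blocked median was -0.17 (camera adjusted p = 0.00125; adjusted p = 0.739 with an estimated correlation). Over meiotic genes with a known GC content, medians in pairs 1, 2 and 3 were -0.30, -0.05 and -0.21 before regression on GC content and gene length and -0.18, -0.09 and -0.08 after it, and camera was not run after it. Of 14 tested pluripotency genes 8 lay below 0 and 6 above (list median -0.12, camera adjusted p = 0.00101; adjusted p = 0.918 with an estimated correlation). Adjusted over the list alone 2 passed, Zfp42 and Dppa4. The pluripotency list did not pass with the block (median -0.09, camera adjusted p = 0.127), where its medians were -0.58, -0.13 and 0.22 in pairs 1, 2 and 3. All 8 Y-linked genes lay below 0 (list median -0.24, camera adjusted p = 0.00520; adjusted p = 0.918 with an estimated correlation). Their medians were -0.29, -0.20 and -0.28 in pairs 1, 2 and 3 (blocked median -0.25, camera adjusted p = 0.000480; adjusted p = 0.739 with an estimated correlation). Eif2s3y, a translation factor gene, had a log2 fold change of -0.25 (SE 0.24) and Zfy2 had -0.84 (SE 0.57), the latter uncertain because it shares sequence with Zfy1. Meiotic prophase and Y-linked genes had 0 members past an adjusted p in either fit, adjusted over the list alone included. Members of both lists were also lower in pair 3 than in pair 1, as given under other observations.

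The remaining lists did not pass in either fit by camera. Without the block, list medians and adjusted p were 0.10 and 0.346 for 25 ERK pathway targets, 0.10 and 0.890 for 16 Wnt pathway targets, 0.08 and 0.147 for 19 retinoic acid pathway genes, 0.09 and 0.219 for 28 cell-cell junction genes, and 0.27 and 0.114 for 15 integrins. They were 0.04 and 0.580 for 23 cholesterol biosynthesis genes, 0.07 and 0.633 for 17 hypoxia targets, -0.05 and 0.219 for 33 nuclear oxidative phosphorylation genes, -0.02 and 0.684 for 5 spermatid genes and -0.03 and 0.876 for 22 germ cell identity and piRNA pathway genes. With the block the retinoic acid median was 0.19 (camera adjusted p = 0.187) and the junction median 0.02 (camera adjusted p = 0.310). Without the block the Wnt list's test pointed lower although its median and mean lay above 0. With the block it pointed higher (median 0.13, camera adjusted p = 0.518). Without the block the means of the stem spermatogonia and germ cell identity lists, at -0.02 and 0.08, differed in sign from their medians. Log2 fold changes by edgeR (adjusted p = 1.0 for each) were 0.52 (SE 0.54) for Fosb and -0.41 (SE 0.47) for Egr2, immediate early genes, 0.68 (SE 0.62) for Lef1 and -0.46 (SE 0.32) for Nkd2. Others were 0.42 (SE 0.24) for Rara, 1.51 (SE 0.83) for Cldn3, 0.90 (SE 0.68) for Itgb7, 0.37 (SE 0.38) for Itga7, -0.20 (SE 0.22) for Sc5d and 0.26 (SE 0.37) for Dhcr7. The germline genes Ddx4, Dazl, Fkbp6 and Dnmt3l had 0.14 (SE 0.50), 0.01 (SE 0.33), 1.82 (SE 0.70) and 0.79 (SE 0.49). Adjusted over the list alone, the blocked fit passed 2 retinoic acid pathway genes (Cyp26a1 lower, Crabp1 higher), 1 junction gene (Cldn3) and 1 integrin (Itga5), both higher, where the fit without the block passed 0 in each of these lists.

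Markers of other somatic cell types gave no call either. Of 9 tested Sertoli cell markers the median was 0.12 (camera adjusted p = 0.809), with 0.85 (SE 0.86) for Clu. Of 10 endothelial markers it was -0.09 (camera adjusted p = 0.537), with 0.54 (SE 0.62) for Eng, which passed in the blocked fit when adjusted over the list alone (0.0188). Of the Leydig cell markers only Star was tested (1.29 ± 0.543 against 1.28 ± 0.397 CPM, SD, n = 3). With 4 macrophage markers tested, too few for a list test, Csf1r stood at 0.368 ± 0.146 against 0.609 ± 0.499 CPM and Lyz2 at 1.29 ± 1.57 against 1.85 ± 1.49 CPM (SD, n = 3).

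Libraries resembled each other by replicate number more than by group. The first 3 principal components of the 500 most variable genes held 66.8%, 19.7% and 8.29% of the variance, and the first set both replicate 3 libraries, at passage 18, apart from the other 4. The nearest library carried the same replicate number for 4 of 6 libraries over these genes and for 6 of 6 over all tested genes. Fibroblast-list reads were highest in the 2 replicate 3 libraries, as given above for each library. Without both replicate 3 libraries the test without a block again called 0 genes (57 at an unadjusted p under 0.05), and 5 lists passed by camera, with extracellular matrix among them.

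**Figure D4:**
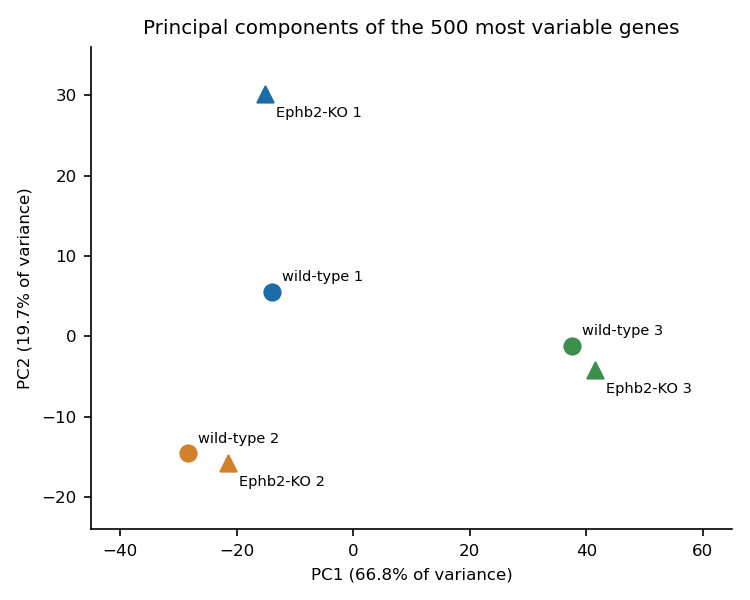
First and second principal components of log2 CPM over the 500 most variable genes, with 1 point per library; circles are wild-type, triangles are labelled Ephb2-KO, and colours mark the replicate number. The first component (66.8% of variance) sets the replicate 3 libraries apart, and libraries of 1 group do not gather together.

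Chromosome-wide shifts were looked for because subcloned lines can differ in chromosome number. Of the autosomes, chromosome 6 in wild-type replicate 1 was the only one with a median shift of 0.15 or more in log2 in any library (0.16 over 750 genes). The largest among the other 113 library and autosome pairs was 0.09 in size. The 12 mitochondrially encoded genes were shifted in each library, by -0.62, 0.32 and -0.53 in wild-type replicates 1, 2 and 3 and by 0.32, 0.80 and -0.22 in the libraries labelled Ephb2-KO. The 10 tested Y chromosome genes were shifted by 0.46 in wild-type replicate 1, 0.22 in Ephb2-KO replicate 1 and -0.47 in Ephb2-KO replicate 3. These shifts are descriptions of single libraries and carry no test.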

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

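The settings joined with the replicate block, the 1-pair-out fits, the fit without genes high in the replicate 3 libraries, the voom fit and the removal of both replicate 3 libraries were chosen after seeing the data, and the other alternatives before. Without the block, the count of genes past the threshold was 0 under RLE scaling, library size alone, both filters, passage as a covariate, glmTreat, non-robust estimation, without shifted chromosomes, with each library left out and without both replicate 3 libraries. It was 4 with DESeq2. The edgeR fit without the block recovered 0% of 2-fold and 0% of 4-fold genes simulated with the real pair means. Its counts of 0 over these settings therefore do not show that no gene changed. With the replicate block the count was 4, and also 4 with RLE scaling and 4 with library size alone. The block gave 19 with DESeq2 (9 higher, 10 lower), 17 with no filter, 3 without 2138 genes at least 2-fold higher in the replicate 3 libraries, and 2 in limma voom with the number as a random effect. All 4 blocked calls were among the 19 and among the 17, and 1 was among the 2. The blocked count was 56 without the replicate 1 libraries, 3 without the replicate 2 libraries and 4 without the replicate 3 libraries, the cause of which was not tested. Of the blocked calls, 4, 3 and 2 were among these. With the strict filter it was 0, since the 4 genes are then not tested.

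Of 28 gene lists, 6 passed by camera. The count was 0 with the correlation estimated per list and 0 with fry. With the block it was 7, and 0 with an estimated correlation and 0 with fry. Camera with an estimated correlation also missed a simulated list shift, so its counts of 0 do not show that no list changed. Other scalings, filters, the passage covariate and blocked fits without 1 pair gave 4 to 7. Without the shifted chromosomes 3 lists passed (meiotic prophase, extracellular matrix and pluripotency). The Y chromosome was among those left out, so the Y-linked list was not tested there, and members of other lists on chromosome 6 were dropped. With single libraries left out 1 to 10 lists passed, the lowest without wild-type replicate 1 and the highest without wild-type replicate 3, the cause of which was not tested. Over all genes, by camera and over each list alone, the block changed no call other than those given here and in the report. Chromosome shifts numbered 10 by library, and 11 over genes of at least 10 CPM.

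Ephb2 kept its sign, never passing, except with single libraries or pairs left out. Its log2 fold change ran from -0.40 without Ephb2-KO replicate 1 to 0.48 without wild-type replicate 2, and was -0.22 in the blocked fit without the replicate 1 libraries. Over its alternatives the adjusted p ran from 0.266 to 1.0. For the other named genes, 625 values under other settings kept their direction and side of the threshold, 30 came past the threshold and 12 changed sign, the cause of which was not tested. Ret was -0.0080 with library size alone. Dazl was -0.015 with library size alone, -0.00074 with the strict filter, -0.022 with the block and -0.027 with passage. Star was 0.0010 with the block and 0.025 with passage. Lhx1 was -0.14 with the block and -0.19 with passage. Ddx4 was -0.057 with the block, and Mki67 was 0.097 with the block and 0.083 with passage. With each library left out in turn, log2 fold changes that crossed 0 ran from -0.071 to 0.61 for Bcl6b, -0.19 to 0.96 for Ccnd1, -0.45 to 0.44 for Ccnd2, -1.07 to 1.58 for Cdkn1a, -0.076 to 1.27 for Col1a1, -0.022 to 1.19 for Csf1r and -0.16 to 0.25 for Dazl. Such values also ran from -0.66 to 0.44 for Ddx4, -0.066 to 0.50 for Dhcr7, -0.057 to 0.76 for Efnb1, -0.21 to 0.59 for Efnb2, -0.074 to 1.05 for Eng, -1.90 to 1.71 for Etv5 and -0.26 to 0.45 for Gfra1. They ran from -0.29 to 0.25 for Id4, -0.023 to 0.60 for Itga7, -0.17 to 1.24 for Itgb7, -0.32 to 0.66 for Kit, -0.29 to 1.08 for Lef1, -0.58 to 0.57 for Lhx1 and -0.36 to 2.24 for Lyz2. The last of these ran from -0.50 to 0.53 for Mki67, -0.17 to 0.97 for Pax7, -0.29 to 0.44 for Ret, -0.31 to 0.27 for Star and -0.43 to 0.057 for Zbtb16. Genes with under about 3 CPM, among them Zfp42, Fxyd2, Star and Lhx1, rest on few counts per library, which limits what depth can show.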

Other observations

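The tests of a lost chromosome segment, of a missing cell type and of feeder-type genes in pair 1 were chosen after the results were seen, as were the comparison of pairs and the splits for the blocked count at an unadjusted p; the other tests were set before their results were seen. Pairs of libraries with the same replicate number differed from each other far more than the groups did. In the blocked fit (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 2 libraries per pair) pair 2 differed from pair 1 in 2516 genes, pair 3 from pair 1 in 6498 and pair 3 from pair 2 in 6928. Over all 15263 tested genes, 1242 were higher and 1274 lower in pair 2 against pair 1. Pair 3 had 3359 higher and 3139 lower against pair 1, and 3732 higher and 3196 lower against pair 2. Counts of list members past that threshold are given for these comparisons, for which no test of whole lists was made. Pair 2 was higher than pair 1, and pair 3 lower than pair 2, in most tested targets of the ERK pathway. Fibroblast growth factor and glial cell line-derived neurotrophic factor can activate this pathway. Of 25 tested, 19 rose and 1 fell in pair 2 against pair 1, and in pair 3 against pair 2, 16 fell and 7 rose. Genes higher in pair 2 than in both other pairs were not counted. Against pair 1, 23 of 41 extracellular matrix genes, 11 of 23 cholesterol biosynthesis genes and 9 of 21 glycolysis genes also rose in pair 2, and 0 fell. Etv5, a transcription factor gene needed for stem cell maintenance, was higher in pair 2 than in pair 1 by a log2 value of 3.29 (SE 0.15, adjusted p = 1.09e-06), Spry4 by 2.50 (SE 0.16, adjusted p = 1.10e-05) and Dusp6 by 1.72 (SE 0.14, adjusted p = 5.52e-05), the latter 2 being feedback inhibitors of the pathway. These differences were shared by the wild-type library and the library labelled Ephb2-KO of the pair, and pairs 1 and 2 were both at passage 20.

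Pair 3, at passage 18, carried more fibroblast-type transcripts and fewer mitosis and cell-cell junction transcripts than pair 2. Against pair 2, 17 of 20 fibroblast or stromal markers rose and 1 fell, 19 of 32 interferon response genes rose and 2 fell, and 17 of 26 cell cycle inhibitors and p53 targets rose and 5 fell. Of 34 mitosis genes 25 fell and 0 rose, of 28 cell-cell junction genes 19 fell and 1 rose, and of 18 stem spermatogonia genes 11 fell and 3 rose (11 and 6 against pair 1). Of 22 germ cell identity and piRNA pathway genes 7 fell and 4 rose against pair 2, and 12 fell and 2 rose against pair 1. Meiotic prophase genes (22 tested) had 3 lower and 0 higher against pair 2, shares no larger than those over all genes. They had 9 lower and 1 higher against pair 1. Y-linked genes (8 tested) had 3 lower and 0 higher against pair 2, and 7 lower and 0 higher against pair 1. Pluripotency genes (14 tested) had 4 lower and 3 higher against pair 2, near the shares over all genes, and 5 lower and 2 higher against pair 1. Against pair 1 the matrix proteoglycan genes Dcn and Lum were higher by log2 values of 3.06 (SE 0.17) and 3.85 (SE 0.23), and the p53 target Cdkn1a by 2.63 (SE 0.15), while Kit was lower (-1.58, SE 0.25, edgeR adjusted p = 0.00126). Mitochondrially encoded transcripts (12 genes) had a blocked median log2 fold change of 0.56 in the libraries labelled Ephb2-KO, with 0.71, 0.48 and 0.34 in pairs 1, 2 and 3, where 33 nuclear oxidative phosphorylation genes had -0.06. Yam1, which overlaps a ribosomal RNA gene, took between 0.353% and 1.98% of counts in a library.

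Ccdc172, A230065H16Rik, Krt18 and Zfp42 were near silent in the 3 libraries labelled Ephb2-KO. Loss of a chromosome segment spanning the neighbours is argued against for the first 3: the lowest of their medians over expressed genes within 1 Mb was -0.017, and Gfra1, 56093 bases from Ccdc172, had a blocked log2 fold change of 0.08 (SE 0.12). Zfp42 had 0 expressed genes within 1 Mb, so for that gene a lost segment cannot be told apart from loss of its transcript alone. A rare cell type missing from those libraries cannot be told apart from loss in the germ cells either: 3 tested genes were at least 8-fold lower in each pair, but these belong to the pattern, and genes of a rare cell type would lie near the floor, where such folds are hard to measure. What stays open is that the lines labelled Ephb2-KO may share an origin or a change limited to single genes. In the real split 5 genes were on-off, against at most 2 in another, and 10 splits are too few for a share under 0.05. On-off means that the lowest library of 1 side was at least 5 times the highest of the other, and at least 0.5 CPM. The off side could hold a few counts, as for Krt18. An effect of the guide itself was not tested.

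Extracellular matrix genes had a median above 0 in each pair, and 30 of 41 were higher in 3 of 3 pairs, but 0 passed over all genes and the list did not pass with an estimated correlation (adjusted p = 0.918, and 0.739 with the block). Camera with an estimated correlation also missed a simulated list shift. Scaling is argued against, as the blocked list median was at least 0.32 under TMM, RLE and library size alone, and GC content and gene length are argued against as the whole cause, as the median over the 3 pairs was 0.33 after regression on both against 0.36 before (0.56, 0.24 and 0.39 in pairs 1, 2 and 3 before, 0.36, 0.34 and 0.23 after). More fibroblast-like feeder cells, a cell type the labels do not name and that sorting before subcloning would not exclude later, are a candidate explanation for part of it: 451 genes outside both lists and at least 4-fold higher in the replicate 3 libraries had a blocked median of 0.22, and 0.11, 0.38 and 0.16 in pairs 1, 2 and 3. Other values were mixed. A set of 577 genes at least 2-fold lower in the replicate 3 libraries had a blocked median of 0.13 (0.38, -0.18 and 0.18 in the pairs). Their rise in pairs 1 and 3 does not follow from feeder cells. Their fall in pair 2, where the 451 genes rose most, goes with such cells. The 26 matrix genes at least 2-fold higher in the replicate 3 libraries had 0.43 (0.62, 0.30 and 0.40). The 15 less than 2-fold higher there had 0.27 (0.39, 0.02 and 0.37). These 15 can still include genes that feeder cells express, so their rise does not decide. In pair 1 the median of the 451 genes was 0.11 (95% bootstrap interval over genes 0.0651 to 0.152) against 0.56 for the matrix list, but after the regression it was 0.17 (0.132 to 0.207) against 0.36, so whether feeder-type cells account for pair 1 cannot be told apart from a matrix change of the germ cells; an effect of the guide on matrix genes stays open and untested.

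Chromosome 6 genes were higher in wild-type replicate 1, with a median shift of 0.16 over 750 genes. GC content and gene length are argued against, since the shift was 0.15 after regression on both. A gain of the whole chromosome in part of the cells is a candidate explanation that these values do not settle. Of the 10 Mb windows, 80% (12 of 15) had a positive median, with medians from -0.30 to 0.35. The chromosome was picked for its positive median, so a majority of positive windows was largely fixed by that choice. The windows therefore cannot tell a gain of the whole chromosome from shifts of parts of it. The level was 1.14-fold that of the other 5 libraries, which 1 extra copy in 28.1% of cells would give. Copy number itself was not measured.

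Splits of the 6 libraries into 3 and 3 were too few, at 10 or at the 4 that part every pair, to give a share under 0.05. Without the block the real split called 0 genes and so did each other split, so 10 of 10 gave as many. For genes at an unadjusted p under 0.05 the real value was 32 and the highest other 4123, with 8 splits as large, and the splits that keep a pair together gave the larger counts, which points to the pairs as a structure of the samples. For gene lists the real value was 6 and the highest other 14, with 7 splits as large. Of the 4 splits that part every pair, the blocked fit called 4 genes in the real split and at most 0 in the others, so 1 was as large. At an unadjusted p under 0.05 the blocked fit gave 987 genes in the real split and 1588 in the highest other, so 2 of these 4 were as large, and for blocked gene lists the values were 7 and 6, so 1 was as large. For on-off genes the real value was 5 and the highest other 2, so 1 of 10 was as large.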
